A study of Mus musculus with 12 samples.

How the data were processed

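RNA from 4 blood vessels of 8-week-old C57BL/6 wild-type mice was hybridised to 12 Affymetrix arrays, 3 per vessel. Per the labels' protocols the mice were untreated, total RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of RNA. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets, and the Partek software, version 6.6, without saying which did what or in what order. The authors deposited a single table of 35556 probe sets with log2 values in every array, whose range and near-equal medians are those of normalized data; the exact normalization is not given in the sources used here. Scanner files were not used here, so background correction and normalization were taken as deposited.

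Probe sets were named from the platform annotation. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none; those with several or none were left out of the gene tests. Of the single-symbol probe sets, 21698 matched the GRCm38.p6 gene table by gene identifier, and 0 symbols changed. For each of 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which gave 19938 genes. Of the 83 pairs of a named gene and a comparison fixed by the rule below, 3 concerned a gene with more than 1 probe set, and in 0 of these did a probe set go the opposite way. No coordinates are given, since the build behind the probe annotation is not given in the sources used here.

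Samples were grouped by the vessel in their labels. A linear model with 1 mean per vessel was fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3, with the package data.table at version 1.17.8 and default empirical Bayes moderation and 8 residual degrees of freedom. A moderated F test compared the 4 vessels and contrasts compared the 6 pairs, each with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. A gene was counted as higher or lower in 1 vessel than in each other where it passed in all 3 contrasts in the same direction. Gene lists for cell types, pathways and developmental regulators, 47 in all, were fixed before the data were examined and tested with limma's camera (preset correlation 0.01) in the 6 contrasts, with 282 tests adjusted together; camera with a correlation estimated from the data was run beside it. List members are counted over all tested genes and also adjusted over the list alone. Lists overlap: Pln stands in the smooth muscle, shared cardiomyocyte and ventricular lists, and Cox7a1 and Cox8b stand in the shared cardiomyocyte and brown adipocyte lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

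Genes to be named were also fixed by rule: for each vessel the 10 genes higher and 5 lower than in each other vessel with the largest smallest difference, for each pair the 8 genes with the largest difference in each direction among those past the threshold, and for each list at most 5 members with the largest difference in the comparison under discussion, with unnamed gene models skipped (6 were skipped among the genes higher in coronary artery). Any Hox gene past the threshold was named too. Ppp1r12b, which completes a count of 3, falls outside the rule and was chosen after its values were seen.

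The procedure was tested on simulated data drawn from normal distributions with each gene's mean and residual spread. For ascending against descending aorta, with 200 changed genes among 19938 in each of 10 runs, it recovered 45% of genes changed 2-fold, 89% of those changed 4-fold, 97.6% at 8-fold and 99.2% at 16-fold, and 5.11% of its calls were false. Genes were drawn independently, so the simulation does not bear on false calls of the list test, in which correlated genes matter. Each gene was also given the same spread in all vessels. In the data the fibroblast list mean, for one, had an SD of 1.41 in ascending and 0.0836 in descending aorta. The simulated recovery and share of false calls may therefore not hold for the real comparison. The alternatives tried, most of them fixed before the data were examined, were a renewed quantile normalization, median centring, leaving out the dimmest 25% of genes, averaging a gene's probe sets, testing every probe set, array weights, an intensity trend with robust variance, the replicate number as a block, a threshold of 0.01, a 2-fold minimum, adjustment over the 6 comparisons together, fitting only the 6 arrays of a pair, and leaving out each array in turn. Added after the data were seen were a fit without 3 arrays that carried transcripts of another tissue (ascending aorta replicate 1, descending aorta replicate 1 and superior mesenteric artery replicate 3) and a fit with the mean of the B cell and T cell lists as a covariate. Arrays kept in the former carried transcripts of other cell types too, so it is not cleared of them. Superior mesenteric artery replicate 2 had a higher B cell mean than replicate 3, and the shared cardiomyocyte list averaged 9.28 ± 0.202 in coronary artery. With 3 arrays per vessel, the number of arrays limits the precision.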

Results

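Gene expression was measured on 12 Affymetrix mouse arrays, each hybridised with total RNA from a blood vessel of untreated 8-week-old wild-type C57BL/6 mice. The arrays fall into 4 vessels of 3 biological replicates: ascending aorta, coronary artery, descending aorta and superior mesenteric artery, the branch of the abdominal aorta that supplies the intestine. The submitters' stated aim was to find expression profiles specific to embryonic origin. The labels call the replicates biological but do not say whether each came from 1 animal or a pool, so the p-values measure the spread between these samples. Values are on the log2 scale, and 19938 genes were tested. Array medians over these genes lay between 4.04 and 4.18, and the number of arrays limits the precision. Below, differences are in log2 units ± SE and levels are means ± SD, with n = 3 arrays in each vessel. Detection calls were not used here, so whether low levels lie above background is not known. The intestinal epithelium list, for one, averaged between 2.97 and 3.07 in the 4 vessels, and a fold against a vessel at background would be a lower bound.

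Vessels differed in the expression of some muscle, fat, mitochondrial and Hox genes. Of the 19938 genes, 942 differed among the 4 vessels at a limma adjusted p under 0.05 in the moderated F test. Heart muscle transcripts separated the coronary artery arrays, in which the shared cardiomyocyte list averaged between 9.06 and 9.46, from the other 9 arrays, in which it averaged between 4.39 and 5.68. Brown adipocyte transcripts averaged 6.37 ± 0.443 in ascending aorta, 7.03 ± 0.265 in descending aorta, 5.39 ± 0.0854 in coronary artery and 4.34 ± 0.283 in superior mesenteric artery. Correlations across genes between arrays of the same vessel had a median of 0.966 over 12 pairs, against 0.931 over 54 pairs from different vessels, with genes not being independent replicates.

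**Figure D1:**
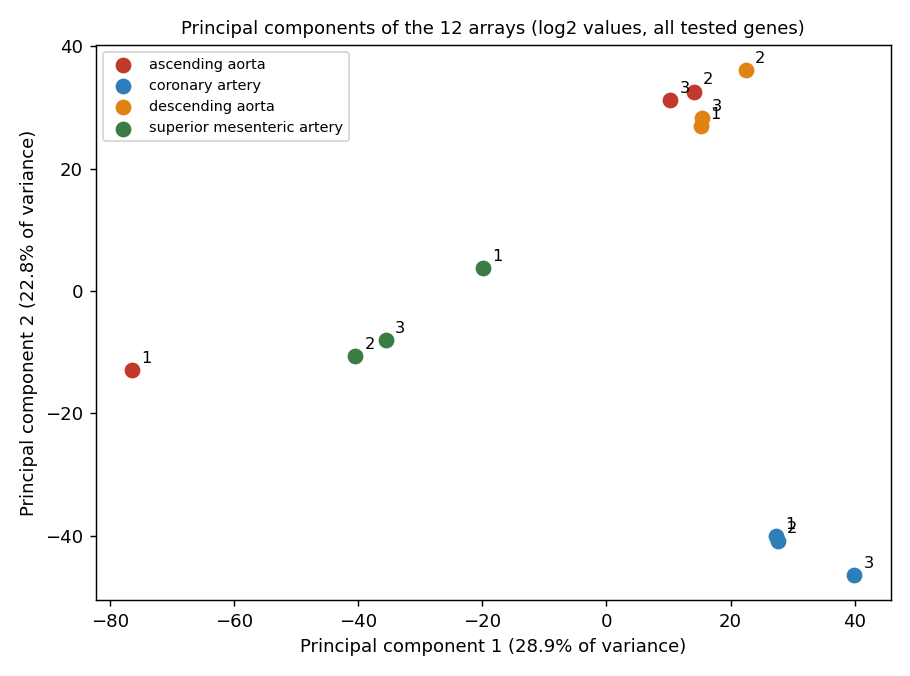
Principal components of the 12 arrays over all tested genes, with component 1 (28.9% of the variance) on the horizontal axis and component 2 (22.8%) on the vertical axis; each point is an array, numbered by replicate. The coronary artery arrays lie lowest on component 2, between -46.4 and -40.0, and ascending aorta replicate 1 lies at -76.5 on component 1, away from replicates 2 and 3 at 14.1 and 10.3.

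Some arrays carried transcripts of other cell types. In ascending aorta replicate 1 the B cell and plasma cell list averaged 7.95 and the T cell and lymph node list 7.62. The B cell list averaged 3.89 and 3.88 in replicates 2 and 3, and the T cell list was at 4.79 in replicate 3. Smooth muscle contractile genes averaged 6.23 in that array against 7.80 and 7.91 in the other ascending aorta arrays, and fibroblast genes 5.82 against 8.34 and 8.19. Its mean correlation across genes was 0.895 with the ascending aorta arrays and 0.920 with the superior mesenteric artery arrays. The B cell list also averaged 6.78 and 6.46 in superior mesenteric artery replicates 2 and 3, against 4.89 in replicate 1. Pancreatic acinar genes averaged 9.32 in superior mesenteric artery replicate 3 and 4.85 and 3.75 in replicates 1 and 2. Smooth muscle genes averaged 9.02 in superior mesenteric artery replicate 1 and 6.41 and 6.81 in replicates 2 and 3. Shared cardiomyocyte genes averaged 5.68 in descending aorta replicate 1, against 4.80 and 4.73 in replicates 2 and 3. The F test gave 1825 genes without ascending aorta replicate 1, 1818 with array weights and 438 at a threshold of 0.01. Without coronary artery replicate 2 or 3 the count was 608 or 602, and without descending aorta replicate 1 or 2 it was 624 or 551.

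**Figure D2:**
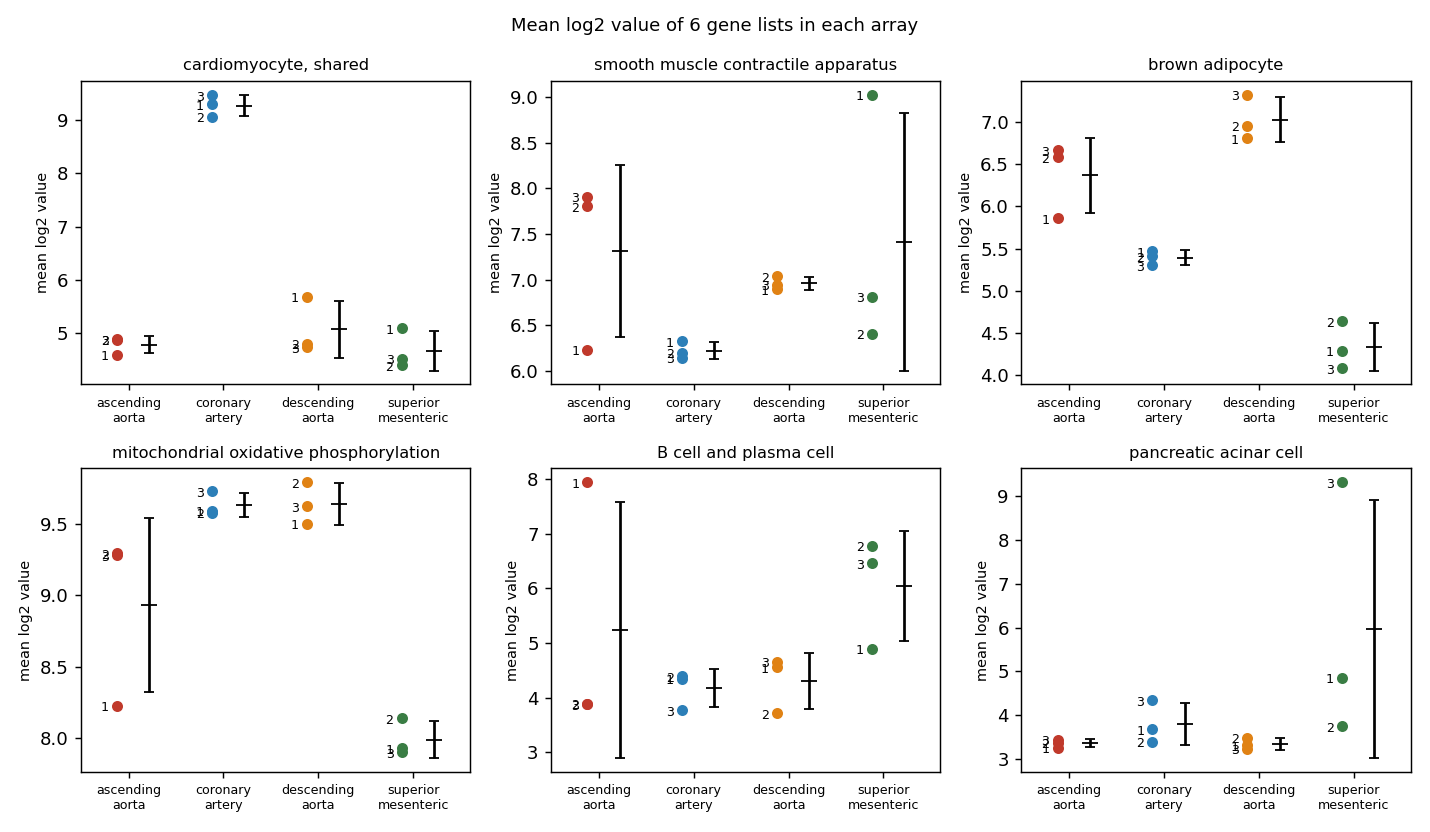
Mean log2 value of 6 gene lists in each array; coloured points are arrays numbered by replicate, and the black bar beside them is the vessel mean ± SD (n = 3). Each panel has its own vertical scale. Shared cardiomyocyte genes lie above 9 in the coronary artery arrays, the B cell list reaches 7.95 in ascending aorta replicate 1, and pancreatic acinar genes reach 9.32 in superior mesenteric artery replicate 3.

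The ascending and descending aorta are segments of 1 vessel whose walls differ in embryonic origin. A pair of HoxC genes and a matrix gene were lower in the ascending segment. Hoxc8, a homeobox gene of trunk patterning, was lower by 2.33 ± 0.31, with a mean of 2.83 ± 0.088 in ascending and 5.16 ± 0.31 in descending aorta (limma adjusted p = 0.0394). Hoxc6, its neighbour in the HoxC cluster, was lower by 2.16 ± 0.24 (limma adjusted p = 0.0121). Fbln7, which encodes an extracellular matrix protein of the fibulin family, averaged 4.11 ± 0.46 in ascending and 6.11 ± 0.079 in descending aorta (limma adjusted p = 0.0121). These were the 3 genes that passed limma's threshold, against 1922 at an unadjusted p under 0.05, and 0 genes were higher in ascending aorta. The limma count was 48 with p-values adjusted over the 6 comparisons together and 6 with the mean of the B cell and T cell lists as a covariate (the lymphoid covariate). It was 0 at a threshold of 0.01, with every probe set tested, with the replicate number as a block or with only the 6 arrays of the pair fitted. Of 23 measured Hox genes of paralogue groups 6 to 13, 2 were lower and 0 higher, or 4 lower when adjusted over the list alone. For that list, limma camera gave adjusted p = 0.00035 (adjusted p = 0.123 with an estimated correlation). Of 14 Hox genes of groups 1 to 5, 0 passed over all genes and 3 were lower when adjusted over the list alone (limma camera adjusted p = 0.00322; adjusted p = 0.365 with an estimated correlation); Hoxb5, the farthest apart, averaged 3.73 ± 0.41 and 5.43 ± 0.36. None of the 37 mitochondrial oxidative phosphorylation genes passed, and 18 were lower in ascending aorta when adjusted over the list alone (limma camera adjusted p = 6.68e-20; adjusted p = 0.448 with an estimated correlation); their mean was 8.23 in replicate 1 and 9.29 and 9.28 in replicates 2 and 3. Shared adipocyte genes had a median difference of -0.90, with 0 of 21 past the threshold, and averaged 6.62, 8.20 and 8.46 in ascending aorta replicates 1, 2 and 3 and 8.60 ± 0.285 in descending aorta. In limma, camera gave adjusted p = 1.74e-08 (adjusted p = 0.593 with an estimated correlation). The B cell and T cell lists had median differences of 0.97 and 1.06, with 0 of 14 and 0 of 16 genes past the threshold (limma camera adjusted p = 0.00599 and 6.69e-05; adjusted p = 0.907 and 0.817 with an estimated correlation). Without ascending aorta replicate 1 the adipocyte median was -0.26, the oxidative phosphorylation median went from -0.67 to -0.34, and the B cell median turned to -0.345 and the T cell median was 0.0608, neither list passing. The B cell median was 1.65 or 1.64 without ascending aorta replicate 2 or 3, and 0.68 without descending aorta replicate 2, where the list did not pass (limma camera adjusted p = 0.0837); the T cell median was 1.72 without ascending aorta replicate 2. The gene count was 0 without ascending aorta replicate 3 or descending aorta replicate 1 or 2, 1 without ascending aorta replicate 2 or descending aorta replicate 3, and 2, Fbln7 and Hoxc6, without ascending aorta replicate 1. Hoxc8 no longer passed when any 1 array of the ascending aorta, descending aorta or coronary artery was left out (limma adjusted p between 0.0781 and 0.234).

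**Figure D3:**
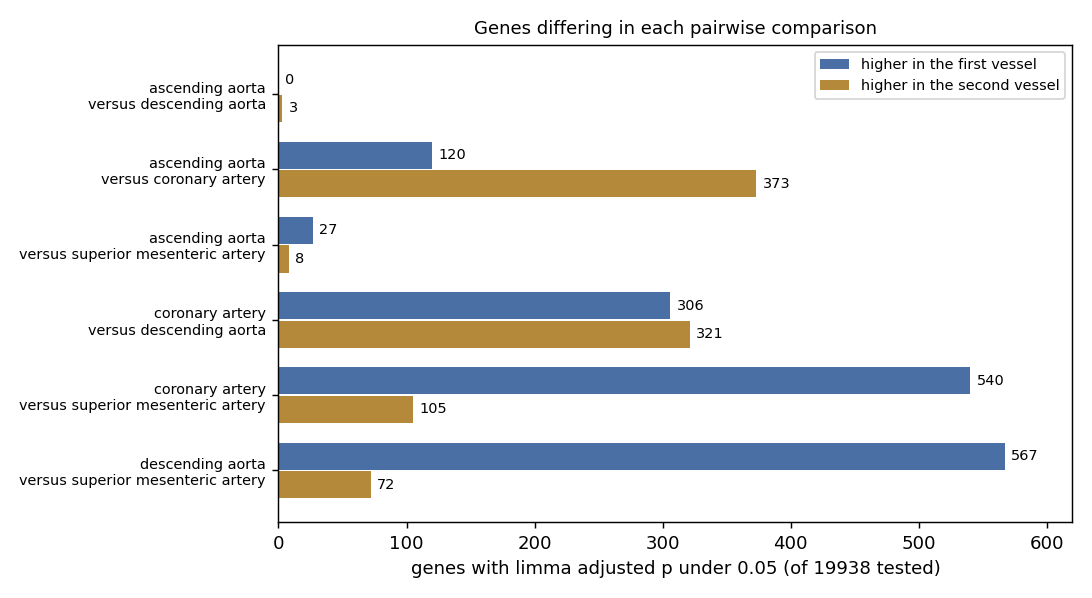
Number of genes with a limma adjusted p under 0.05 in each pairwise comparison, out of 19938 tested; the upper bar of each pair counts genes higher in the first vessel named and the lower bar genes higher in the second. The comparison of ascending with descending aorta has 0 and 3 genes, and that of descending aorta with superior mesenteric artery 567 and 72.

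Between ascending aorta and coronary artery, most shared cardiomyocyte genes were higher in coronary artery, and single genes of brown fat and smooth muscle were higher in ascending aorta. Myl2, the ventricular myosin regulatory light chain, averaged 12.09 ± 0.14 in coronary artery and 3.27 ± 0.20 in ascending aorta, a 453-fold difference (limma adjusted p = 2.02e-10). Nppa, which encodes the atrial natriuretic peptide precursor, was 149-fold higher in coronary artery (limma adjusted p = 2.61e-08), Tnnc1, cardiac troponin C, 192-fold (limma adjusted p = 3.37e-06), and Hamp, which encodes hepcidin, 160-fold (limma adjusted p = 0.00273). Smpx, Csrp3, Actc1 and Pln, all transcripts of striated muscle, were between 140-fold and 206-fold higher there. Ucp1, the uncoupling protein of brown fat, averaged 10.93 ± 0.31 in ascending aorta and 4.77 ± 1.51 in coronary artery, a 71.6-fold difference (limma adjusted p = 0.00105). In all, 120 genes were higher and 373 lower in ascending aorta. The total was 887 with array weights, 877 with the lymphoid covariate, 252 with only the 6 arrays of the pair fitted and 227 at a threshold of 0.01.

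By group, 25 of 30 measured shared cardiomyocyte genes were lower in ascending aorta than in coronary artery, or 27 adjusted over the list alone. By limma camera this was adjusted p = 1.35e-60 (adjusted p = 0.00723 with an estimated correlation). Of 12 atrial cardiomyocyte genes, 7 were lower, among them Myl7 by 6.89 ± 1.18 and Myl4 by 5.79 ± 0.74 (7 lower and 1 higher adjusted over the list alone). As a group, limma camera gave adjusted p = 6.15e-08 (adjusted p = 0.0656 with an estimated correlation). Of 10 ventricular genes 4 were lower (6 lower and 1 higher adjusted over the list alone). Over the whole list, limma camera gave adjusted p = 1.69e-05 (adjusted p = 0.0435 with an estimated correlation). Among 25 smooth muscle contractile genes, 4 were higher in ascending aorta: the integrin subunit gene Itga8 by 4.18 ± 0.82, the calponin gene Cnn1 by 4.13 ± 0.84, the smooth muscle myosin heavy chain gene Myh11 by 4.10 ± 0.84 and the actin gene Acta2 by 2.92 ± 0.63. The 3 members that were lower, Pln, Des and Ppp1r12b, are also expressed in heart muscle; 14 were higher and 4 lower adjusted over the list alone. As a set, limma camera gave adjusted p = 7.16e-05 (adjusted p = 0.864 with an estimated correlation). Shared adipocyte genes were higher for 7 of 21, including Pck1 by 3.36 ± 0.38 and the lipid droplet gene Plin1 by 2.54 ± 0.41 (16 higher and 1 lower adjusted over the list alone). Tested together, limma camera gave adjusted p = 2.7e-11 (adjusted p = 0.448 with an estimated correlation). Of the 13 brown adipocyte genes, 3 were higher, Ucp1, Cidea and Dio2, or 5 adjusted over the list alone. For the group, limma camera gave adjusted p = 0.00931 (adjusted p = 0.594 with an estimated correlation), and the list did not pass without ascending aorta replicate 2 or 3 (adjusted p = 0.0548 or 0.0532). Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, was 13.9-fold higher in ascending aorta (limma adjusted p = 0.000489). Of 21 genes for second heart field and cardiac transcription factors, 6 were lower, led by Tbx20 by 3.26 ± 0.27 and Tbx5 by 3.17 ± 0.31, which heart muscle also expresses (7 lower and 1 higher adjusted over the list alone). For that list, limma camera gave adjusted p = 0.000442 (adjusted p = 0.187 with an estimated correlation). Epicardial and mesothelial genes were lower for 6 of 17, including Tcf21, a transcription factor of epicardium and cardiac fibroblasts, by 2.77 ± 0.44 (16 lower adjusted over the list alone). In limma, camera gave adjusted p = 7.27e-14 (adjusted p = 0.365 with an estimated correlation). The counts were 404 higher and 364 lower, with 13 smooth muscle genes higher, without ascending aorta replicate 1. Without coronary artery replicate 1, 2 or 3 the total was 326, 280 or 251. Itga8, Cnn1, Myh11 and Acta2 did not pass without ascending aorta replicate 2 or 3 or any 1 coronary artery array, nor Acta2 without any 1 descending aorta array (limma adjusted p between 0.0502 and 0.138).

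Ascending aorta and superior mesenteric artery differed in single genes of brown fat and mitochondria, among others. Ucp1 was 81.7-fold higher in ascending aorta, with means of 10.93 ± 0.31 and 4.58 ± 1.95 (limma adjusted p = 0.00885), and Cidea, a lipid droplet protein gene of brown fat, was 21.4-fold higher (limma adjusted p = 0.000898). The cytochrome oxidase subunit genes Cox7a1 and Cox8b were higher by 4.74 ± 0.55 and 3.68 ± 0.41, and the fatty acid binding protein gene Fabp3 by 3.80 ± 0.35 (limma adjusted p = 0.00483, 0.00472 and 0.00104). Pcp4, which encodes a calmodulin-binding protein, was lower in ascending aorta, at 4.51 ± 0.49 against 8.89 ± 1.52, a 20.7-fold difference (limma adjusted p = 0.00877). In all, 27 genes were higher and 8 lower in ascending aorta. The limma total was 0 with only the 6 arrays of the pair fitted, 14 at a threshold of 0.01, 20 with every probe set tested, 56 after a renewed quantile normalization, 123 with p-values adjusted over the 6 comparisons together, 255 with the lymphoid covariate, 330 without the 3 arrays that carried transcripts of another tissue and 443 with array weights.

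Of 13 measured brown adipocyte genes, 4 were higher in ascending aorta than in superior mesenteric artery, or 7 adjusted over the list alone. By limma camera this was adjusted p = 9.2e-18 (adjusted p = 0.0435 with an estimated correlation). Among 21 shared adipocyte genes 1 was higher, Pck1, by 2.52 ± 0.38, or 13 adjusted over the list alone. As a group, limma camera gave adjusted p = 7.64e-20 (adjusted p = 0.245 with an estimated correlation). Gpd1 was higher by 3.49 ± 0.47 and the mitochondrial gene Chchd10 by 2.35 ± 0.34. Of 37 oxidative phosphorylation genes, 1 was higher, Cox5a, by 1.39 ± 0.23, or 32 adjusted over the list alone. Over the whole list, limma camera gave adjusted p = 3.55e-38 (adjusted p = 0.218 with an estimated correlation). The 3 higher shared cardiomyocyte genes were Cox7a1, Cox8b and Fabp3, which brown fat also expresses. Of 14 Hox genes of groups 1 to 5, 0 passed in limma, also when adjusted over the list alone. As a list they had a median difference of -0.21 (limma camera adjusted p = 0.00319; adjusted p = 0.365 with an estimated correlation), and did not pass without ascending aorta replicate 1 or superior mesenteric artery replicate 1 (adjusted p = 0.261 or 0.107), with a median of -0.12 without the latter. Of 22 endothelial genes 0 passed and 4 were lower in ascending aorta adjusted over the list alone (median difference -0.60; limma camera adjusted p = 9e-06; adjusted p = 0.789 with an estimated correlation). That list did not pass without ascending aorta replicate 1 or superior mesenteric artery replicate 1 (adjusted p = 0.162 or 0.221), with medians of -0.16 without the latter and -1.11 without superior mesenteric artery replicate 2. Cxcl12, a chemokine gene, was higher by 1.46 ± 0.23 (limma adjusted p = 0.0333). The 8 lower genes were Pcp4, Ddah1, which degrades an inhibitor of nitric oxide synthase, Tmem88, Abcg2, the prolyl hydroxylase gene Egln3, Spon2, Adgrg6 and Nrarp, a Notch pathway regulator; Ddah1 was lower by 2.62 ± 0.35 and Nrarp by 1.19 ± 0.20. The B cell list mean was 7.95 in ascending aorta replicate 1 and 6.78 and 6.46 in superior mesenteric artery replicates 2 and 3. Pancreatic acinar genes had a median difference of -2.89 (limma camera adjusted p = 2.64e-11), or -0.713 without superior mesenteric artery replicate 3. Macrophage and monocyte genes were at -0.516 (limma camera adjusted p = 6.08e-05) and did not pass without superior mesenteric artery replicate 2 (adjusted p = 0.213). Neither list held with an estimated correlation. Without ascending aorta replicate 1, 484 genes were higher and 144 lower, with 33 of 37 oxidative phosphorylation genes higher, and without superior mesenteric artery replicate 1 there were 77 genes. The count was 7 or 6 without ascending aorta replicate 2 or 3, 8 without superior mesenteric artery replicate 3, 19 without coronary artery replicate 1 or 3 or descending aorta replicate 2, 21 without descending aorta replicate 1 and 22 without descending aorta replicate 3. With 1 array left out, 12 of 17 named genes did not pass in at least 1 of the 12 sets (limma adjusted p between 0.0506 and 0.232), among them Adgrg6 in 11, Nrarp in 10, Abcg2 and Spon2 in 9, Ucp1 and Ddah1 in 3 and Pcp4 in 2.

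Between coronary artery and descending aorta, most shared cardiomyocyte and shared adipocyte genes and some Hox genes differed. Myl2 was 361-fold higher in coronary artery (limma adjusted p = 3.21e-10) and Tnnc1 154-fold (limma adjusted p = 5.38e-06). Myl3, the ventricular essential light chain, was higher by 6.66 ± 0.43 (limma adjusted p = 2.26e-06). Ucp1 was lower in coronary artery by 6.72 ± 0.83, a 106-fold difference (limma adjusted p = 0.000492), and Sfrp4, a secreted inhibitor of Wnt signalling, by 5.19 ± 0.77, a 36.5-fold difference (limma adjusted p = 0.00205). Hoxc8, Hoxb6, Hoxb5, Hoxc6 and Hoxa5 were lower in coronary artery by 2.29 ± 0.31, 2.19 ± 0.33, 2.04 ± 0.44, 1.80 ± 0.24 and 1.75 ± 0.39 (limma adjusted p between 0.00081 and 0.0298). With 1 array left out, Hoxa5 did not pass in 5 and Hoxb5 in 6 of 12 sets (limma adjusted p up to 0.128 and 0.116). In all, 306 genes were higher and 321 lower in coronary artery. The total was 1261 with only the 6 arrays of the pair fitted, 1095 with array weights, 1015 with the lymphoid covariate and 322 at a threshold of 0.01.

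Of 30 shared cardiomyocyte genes, 26 were higher in coronary artery than in descending aorta, or 28 adjusted over the list alone. As a set, limma camera gave adjusted p = 5.55e-65 (adjusted p = 0.00723 with an estimated correlation). The atrial list had 7 of 12 higher, including Myl4 by 4.57 ± 0.74 (7 higher and 1 lower adjusted over the list alone; limma camera adjusted p = 1.61e-08; adjusted p = 0.0565 with an estimated correlation), and the ventricular list 3 of 10 (5 higher and 1 lower adjusted over the list alone). The ventricular list had, by limma camera, adjusted p = 6.01e-08 (adjusted p = 0.0202 with an estimated correlation). Shared adipocyte genes were lower for 16 of 21, with Pck1 lower by 4.34 ± 0.38, Plin1 by 3.47 ± 0.41 and the fatty acid synthase gene Fasn by 3.12 ± 0.71 (19 adjusted over the list alone). For the group, limma camera gave adjusted p = 2.59e-24 (adjusted p = 0.187 with an estimated correlation). Of 13 brown adipocyte genes, 5 were lower, or 7 adjusted over the list alone. For that list, limma camera gave adjusted p = 7.61e-07 (adjusted p = 0.187 with an estimated correlation). In the Hox lists, 3 of 23 genes of groups 6 to 13 were lower (6 adjusted over the list alone; limma camera adjusted p = 0.029; adjusted p = 0.367 with an estimated correlation; not past the threshold without ascending aorta replicate 1, coronary artery replicate 2 or descending aorta replicate 2), as were 2 of 14 of groups 1 to 5 (6 adjusted over the list alone). Groups 1 to 5 had, by limma camera, adjusted p = 0.000139 (adjusted p = 0.191 with an estimated correlation). Cardiac transcription factor genes were higher for 5 of 21, with Tbx20 9.37-fold higher and Gata4 3.57-fold (8 adjusted over the list alone). By limma camera this was adjusted p = 3.47e-06 (adjusted p = 0.11 with an estimated correlation). The endothelial genes Emcn, Kdr and Flt1 were higher in coronary artery by 2.46 ± 0.50, 2.07 ± 0.37 and 1.51 ± 0.35, as 3 of 22 endothelial genes (5 adjusted over the list alone). As a group, limma camera gave adjusted p = 0.00138 (adjusted p = 0.868 with an estimated correlation). Of 27 receptors and channels for vasoactive signals, 3 differed, also when adjusted over the list alone, while the list as a whole did not pass (limma camera adjusted p = 0.258). Npr3, the natriuretic peptide clearance receptor, was higher in coronary artery by 2.21 ± 0.43, Agtr1a, an angiotensin II receptor, by 1.73 ± 0.22, and the prostaglandin receptor gene Ptger3 was lower by 2.04. When ascending aorta replicate 1, which shares only the estimate of the spread, was left out, 455 genes were higher and 601 lower. The total was 402, 385 or 414 without coronary artery replicate 1, 2 or 3, and 385 or 324 without descending aorta replicate 1 or 2. With 1 array left out, 5 of 26 named genes did not pass in at least 1 of the 12 sets (limma adjusted p between 0.0505 and 0.141): Cnn1 in 6, Myl7 in 5, Ptprj and Skap2 in 4 and Tmem45b in 3. Myl4 and Myl7 stood at 8.29 and 9.24 in descending aorta replicate 1, against at most 5.19 and 4.86 in its replicates 2 and 3.

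**Figure D4:**
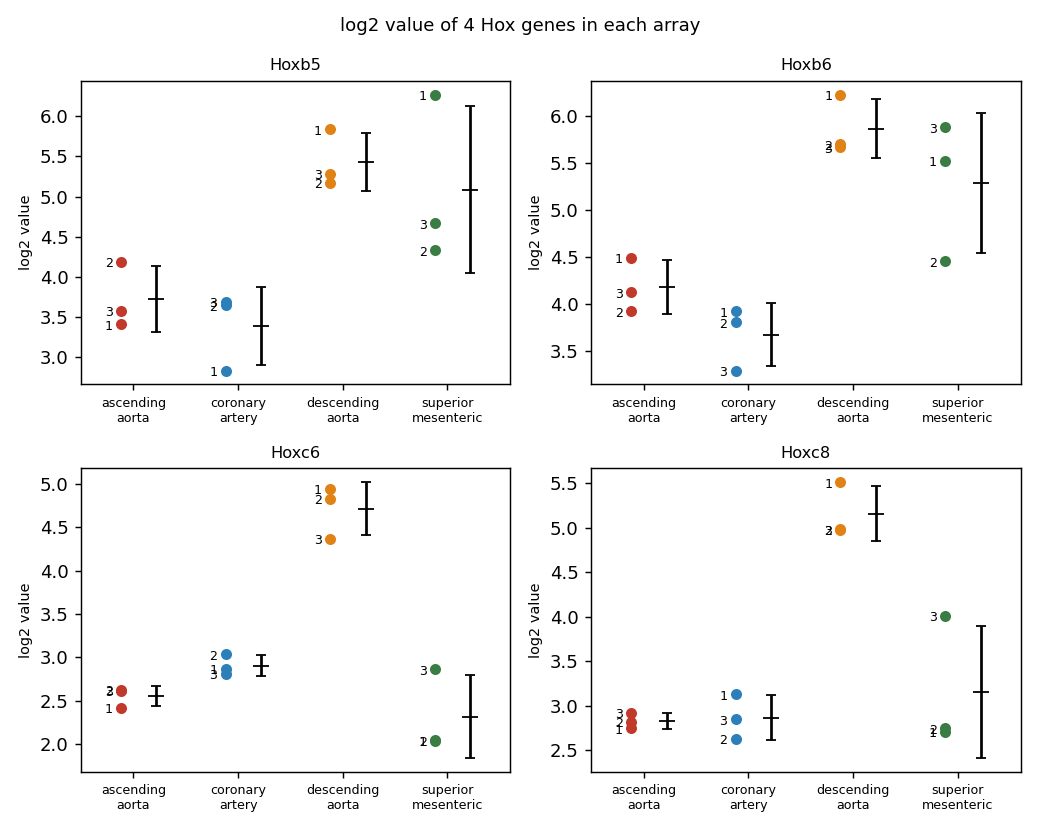
log2 value of Hoxb5, Hoxb6, Hoxc6 and Hoxc8 in each array; coloured points are arrays numbered by replicate, and the black bar beside them is the vessel mean ± SD (n = 3). Each panel has its own vertical scale. Hoxc8 averages 5.16 in descending aorta and 2.83, 2.87 and 3.15 in ascending aorta, coronary artery and superior mesenteric artery, while Hoxb6 averages 5.86 and 5.29 in descending aorta and superior mesenteric artery and 4.18 and 3.67 in ascending aorta and coronary artery.

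Coronary artery and superior mesenteric artery differed in heart muscle and mitochondrial genes, with 540 genes higher and 105 lower in coronary artery. Myl2 was 338-fold higher in coronary artery (limma adjusted p = 3.68e-10) and Tnnc1 215-fold (limma adjusted p = 3.17e-06). Of 37 oxidative phosphorylation genes, 36 were higher in coronary artery, among them the cytochrome c gene Cycs by 2.50 ± 0.36 and the succinate dehydrogenase gene Sdhb by 2.22 ± 0.35 (37 adjusted over the list alone). Over the whole list, limma camera gave adjusted p = 2.96e-46 (adjusted p = 0.187 with an estimated correlation). Pcp4 was higher in superior mesenteric artery, at 8.89 ± 1.52 against 4.50 ± 0.13, a 20.9-fold difference (limma adjusted p = 0.000637). Foxf1, a transcription factor of the mesenchyme around the gut, was 5.28-fold higher in superior mesenteric artery (limma adjusted p = 0.0111).

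Other groups differed between this pair. Shared cardiomyocyte genes were higher in coronary artery for 27 of 30, or 30 adjusted over the list alone (limma camera adjusted p = 5.78e-66; adjusted p = 0.00723 with an estimated correlation), atrial genes for 7 of 12, or 7 adjusted over the list alone (limma camera adjusted p = 2.17e-09; adjusted p = 0.046 with an estimated correlation), and ventricular genes for 4 of 10, or 7 adjusted over the list alone. Ventricular genes had, by limma camera, adjusted p = 3.66e-07 (adjusted p = 0.0236 with an estimated correlation). Smooth muscle contractile genes Cnn1, Myh11 and the enteric actin gene Actg2 were lower in coronary artery by 3.84 ± 0.84, 3.49 ± 0.84 and 3.46 ± 0.69, and Pln was higher; of 25 members, 2 were higher and 14 lower adjusted over the list alone. Tested together, limma camera gave adjusted p = 3.73e-05 (adjusted p = 0.851 with an estimated correlation). The list averaged 9.02, 6.41 and 6.81 in superior mesenteric artery replicates 1, 2 and 3 and 6.22 ± 0.0931 in coronary artery. Without superior mesenteric artery replicate 1 its median difference went from -1.58 to -0.78 and it did not pass (limma camera adjusted p = 0.0595). Thbs1, a matricellular thrombospondin, was lower by 2.89 ± 0.55, Grem1, a secreted antagonist of bone morphogenetic proteins, by 2.84 ± 0.70 and the complement gene C7 by 2.54 ± 0.47 (limma adjusted p = 0.011, 0.0479 and 0.00932). Hoxb6 was lower in coronary artery by 1.61 ± 0.33 (limma adjusted p = 0.0179), as 1 of 23 Hox genes of groups 6 to 13, while the list as a whole did not pass (limma camera adjusted p = 0.903). Hoxb6 itself did not pass without coronary artery replicate 2 or 3 or superior mesenteric artery replicate 1 or 3 (limma adjusted p up to 0.103). Of 14 Hox genes of groups 1 to 5, 0 passed in limma and 3 were lower in coronary artery adjusted over the list alone (median difference -0.39; limma camera adjusted p = 0.000818; adjusted p = 0.26 with an estimated correlation). Pancreatic acinar genes had a median difference of -2.23, with 0 of 14 past the threshold (limma camera adjusted p = 1.22e-05; adjusted p = 0.734 with an estimated correlation), and averaged 9.32 in superior mesenteric artery replicate 3, without which the median was -0.47. B cell genes had a median difference of -1.80, with 0 of 14 past the threshold and 1 lower adjusted over the list alone. For the group, limma camera gave adjusted p = 6.69e-05 (adjusted p = 0.811 with an estimated correlation). The total was 1129 with array weights and 303 at a threshold of 0.01. Without ascending aorta replicate 1, 835 genes were higher and 457 lower, and the total was 412 or 314 without coronary artery replicate 2 or 3 and 364 without superior mesenteric artery replicate 3. With 1 array left out, 10 of 29 named genes did not pass in at least 1 of the 12 sets (limma adjusted p between 0.05 and 0.187), among them Grem1 in 9, Myh11 in 8, Slc1a5 in 6 and Cnn1 in 5.

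Descending aorta exceeded superior mesenteric artery in brown fat, adipocyte and mitochondrial genes, with 567 genes higher and 72 lower. Ucp1 was 120-fold higher in descending aorta, at 11.49 ± 0.17 against 4.58 ± 1.95 (limma adjusted p = 0.00107), Cox7a1 46.7-fold (limma adjusted p = 0.000582) and Cidea 42.4-fold (limma adjusted p = 4.33e-05). Of 37 oxidative phosphorylation genes, 34 were higher, or 36 adjusted over the list alone, with Cycs higher by 2.65 ± 0.36 and Sdhb by 2.42 ± 0.35. For that list, limma camera gave adjusted p = 1.1e-46 (adjusted p = 0.187 with an estimated correlation). Hoxc6 was higher in descending aorta by 2.39 ± 0.24 (limma adjusted p = 0.000582), and Hoxc8 averaged 5.16 ± 0.31 against 3.15 ± 0.74 (limma adjusted p = 0.00389). Pcp4 was lower in descending aorta, by 4.50 ± 0.56, and Foxf1 by 1.86 ± 0.46 (limma adjusted p = 0.00129 and 0.0463).

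Brown adipocyte genes were higher in descending aorta than in superior mesenteric artery for 8 of 13, or 12 adjusted over the list alone. In limma, camera gave adjusted p = 2.31e-16 (adjusted p = 0.0443 with an estimated correlation). Shared adipocyte genes were higher for 14 of 21, or 19 adjusted over the list alone, including Pck1 by 3.49 ± 0.38 and Pparg, the adipocyte nuclear receptor, by 2.71 ± 0.41. By limma camera this was adjusted p = 4.82e-24 (adjusted p = 0.187 with an estimated correlation). The gap junction gene Gja5, present in arterial endothelium, was higher by 3.86 ± 0.82 (limma adjusted p = 0.0226). The endothelium list, which does not hold Gja5, went the other way: of 22 genes, Plvap and Robo4 were lower in descending aorta by 1.65 ± 0.34 and 1.47 ± 0.35, with 6 lower and 1 higher adjusted over the list alone. Its median difference was -0.76 (limma camera adjusted p = 0.000134; adjusted p = 0.85 with an estimated correlation). The list averaged 7.31, 5.55 and 6.46 in superior mesenteric artery replicates 1, 2 and 3, and its median was -0.325 without replicate 1, where it did not pass (limma camera adjusted p = 0.0983), and -1.20 without replicate 2. None of 8 lymphatic endothelial genes passed and 3 were lower adjusted over the list alone (median difference -0.83, or -0.47 without superior mesenteric artery replicate 1; limma camera adjusted p = 0.00243; adjusted p = 0.491 with an estimated correlation). Of 13 capillary and venous endothelial genes 4 were higher in descending aorta, Rgcc, Lpl, Fabp4 and Cd36, of which Lpl, Fabp4 and Cd36 are also expressed by adipocytes (5 higher adjusted over the list alone). By limma camera this was adjusted p = 0.0051 (adjusted p = 0.376 with an estimated correlation), with a median of 0.26, or 0.12 without descending aorta replicate 2. Of 22 neural crest regulators, Twist1 and Snai2 were higher in descending aorta by 1.96 ± 0.47 and 1.23 ± 0.23 (3 adjusted over the list alone), while the list as a whole did not pass (limma camera adjusted p = 0.502). The 2 Hox genes were among 23 of groups 6 to 13, with 2 adjusted over the list alone. As a group, limma camera gave adjusted p = 0.0409 (adjusted p = 0.408 with an estimated correlation), and the list did not pass in 5 of the 12 sets with 1 array left out (adjusted p between 0.0515 and 0.135). Genes lower in descending aorta included Grem1, 7.98-fold lower, Ddah1 by 2.63 ± 0.35, Bst1 by 2.60 ± 0.48, Gpr182 by 2.54 ± 0.46, Adgrf5 by 2.49 ± 0.41, the leptin receptor gene Lepr by 2.29 ± 0.47 and the integrin subunit gene Itga6 by 2.22 ± 0.44. Lists of other cell types were lower too. Pancreatic acinar genes had a median of -2.67 (limma camera adjusted p = 3.78e-08), or -0.846 without superior mesenteric artery replicate 3. Macrophage and monocyte genes had a median of -0.741 (limma camera adjusted p = 0.00221) and did not pass without superior mesenteric artery replicate 2 (adjusted p = 0.312). Neither list held with an estimated correlation. The total was 1356 with array weights and 235 at a threshold of 0.01. Leaving out ascending aorta replicate 1 gave 970 genes higher and 391 lower. The total was 365, 218 or 361 without descending aorta replicate 1, 2 or 3 and 272 without superior mesenteric artery replicate 3. With 1 array left out, 8 of 22 named genes did not pass in at least 1 of the 12 sets (limma adjusted p between 0.0529 and 0.224), among them Nrarp in 10, Grem1 in 8, Gja5 in 5 and Lepr in 4.

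Genes that set 1 vessel apart from each of the other 3 were mostly coronary artery genes. By limma, 212 genes were higher in coronary artery than in each other vessel, and 32 of these belonged to the cardiomyocyte lists, which have 50 measured members between them. The 10 with the largest smallest difference were Myl2, Tnnc1, Myl3, Hamp, Nppa, Csrp3, Smpx, Cox6a2, Myoz2 and Myl7. Myl7, the last of these, was higher by at least 5.82, its difference from descending aorta. That difference was 7.35 without descending aorta replicate 1 and did not pass without descending aorta replicate 2 or 3 or any 1 coronary artery array (limma adjusted p between 0.0547 and 0.102). In the coronary artery arrays, the ventricular Myl2 averaged 12.09 ± 0.14 and the atrial Myl7 11.99 ± 0.42. The 9 genes lower in coronary artery included Cnn1, Angptl4, which encodes an inhibitor of lipoprotein lipase, Ptprj, the glutamine transporter gene Slc1a5 and Skap2, with smallest differences from 3.76 for Cnn1 to 1.16 for Skap2. Hoxc8, Fbln7 and Hoxc6 were the 3 genes higher in descending aorta than in each other vessel, Fbln7 by at least 1.89 and Hoxc6 by at least 1.80. Pcp4, Ddah1 and Nrarp were the 3 higher in superior mesenteric artery, by at least 4.38, 1.82 and 0.81. Of 16 genes lower in superior mesenteric artery than in each other vessel, Cox7a1, Fabp3, Cox8b, Chchd10 and Hadhb, all of mitochondrial metabolism or fatty acid handling, differed most, from 4.74 for Cox7a1 to 1.91 for Hadhb. By limma, 0 genes were higher and 0 lower in ascending aorta than in each other vessel, against 49 and 39 with an unadjusted p under 0.05 in all 3 comparisons, and 0 were lower in descending aorta, against 52. With every probe set tested, at a threshold of 0.01 or with the replicate number as a block, limma gave 0 genes higher in descending aorta. With array weights 32 were higher and 160 lower in superior mesenteric artery and 32 lower in coronary artery. Without ascending aorta replicate 1, 63 genes were higher and 207 lower in superior mesenteric artery and 47 were lower in coronary artery. The number higher in descending aorta was 0 without ascending aorta replicate 3 or descending aorta replicate 1 or 2, and 1 without ascending aorta replicate 2 or descending aorta replicate 3. In superior mesenteric artery, 27 or 6 genes were higher without its replicate 1 or 2, 1 without its replicate 3 or coronary artery replicate 3, and 0 without ascending aorta replicate 2 or 3. The number lower there was 3 without ascending aorta replicate 2 or 3 or its own replicate 3, 6 without its replicate 2 or coronary artery replicate 3, 7 without coronary artery replicate 1 or descending aorta replicate 2 or 3, 9 without descending aorta replicate 1 and 10 without coronary artery replicate 2. Genes lower in coronary artery numbered 5, 1 or 0 without its replicate 1, 2 or 3, 4, 4 or 5 without descending aorta replicate 1, 2 or 3, and 2 without superior mesenteric artery replicate 3.

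In the lists of developmental regulators, which the stated aim concerns, most members did not pass the threshold. The share could still exceed that of all genes. Between ascending aorta and coronary artery, 6 of 21 cardiac and second heart field transcription factors passed, against 493 of all 19938 genes. Among 16 somite and paraxial mesoderm regulators, Meox1 was higher in coronary artery than in descending aorta by 1.62 ± 0.36 and lower in descending aorta than in superior mesenteric artery by 1.63 ± 0.36 (limma adjusted p = 0.0279 and 0.0272). In the splanchnic mesoderm list of 15 genes, Foxf1 averaged 5.99 ± 1.25 in superior mesenteric artery, 4.79 ± 0.23 in ascending aorta, 4.12 ± 0.27 in descending aorta and 3.59 ± 0.22 in coronary artery. None of the 22 neural crest regulators passed limma's threshold between ascending and descending aorta, where Twist1 averaged 5.27 ± 1.29 and 6.03 ± 0.11. Of the 21 cardiac and second heart field transcription factors, Tbx20, Tbx5, Hopx and Gata4 were higher in coronary artery than in each other vessel, with Tbx20 averaging 6.26 ± 0.45 there and between 2.60 and 3.03 elsewhere. Cardiomyocytes also express these factors, and the shared cardiomyocyte list averaged 9.28 in coronary artery and between 4.67 and 5.07 in the other vessels. Across the 47 gene lists and 6 comparisons, limma's camera with its preset correlation of 0.01 called 96 of 282 tests at an adjusted p under 0.05, and 9 of these held with an estimated correlation: the shared cardiomyocyte and ventricular lists in the 3 coronary artery comparisons, the atrial list between coronary and superior mesenteric artery, and the brown adipocyte list in both aortic segments against superior mesenteric artery.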

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

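The fit without 3 arrays that carried transcripts of another tissue and the fit with the lymphoid mean as covariate were chosen after the data were seen; the other alternatives were fixed before. Over the named genes, each tried in 18 settings, 1946 results kept direction and side of the threshold, 232 kept the direction only and 0 reversed. Array weights, the probe-set choices, the dim filter, the other thresholds and adjustment, and the fit of only a pair's arrays were not among these settings. The named genes were chosen for large differences in these data, so the lack of reversals tells little. Over the lists the numbers were 1574, 231 and 17. With array weights the counts were 1818 genes among the 4 vessels, 887 for ascending aorta against coronary artery, 443 for ascending aorta against superior mesenteric artery, 1095 for coronary artery against descending aorta, 1129 for coronary against superior mesenteric artery and 1356 for descending aorta against superior mesenteric artery; 32 genes were lower in coronary artery, and 32 higher and 160 lower in superior mesenteric artery, than in each other vessel. At an adjusted p under 0.01, a stricter threshold by construction, the counts in the same order, with ascending against descending aorta second, were 438, 0, 227, 14, 322, 303 and 235, with 141 genes higher and 0 lower in coronary artery, 0 higher in descending aorta, and 1 higher and 5 lower in superior mesenteric artery, than in each other vessel. For every probe set tested, the counts were 0 for ascending against descending aorta, 20 for ascending aorta against superior mesenteric artery, 0 higher in descending aorta and 10 lower in superior mesenteric artery. Adjusting over the 6 comparisons together gave 48 genes for ascending against descending aorta and 123 for ascending aorta against superior mesenteric artery. Fitting only the 6 arrays of a pair gave 0 for ascending against descending aorta, 252 for ascending aorta against coronary artery, 0 for ascending aorta against superior mesenteric artery and 1261 for coronary artery against descending aorta. A renewed quantile normalization gave 56 genes for ascending aorta against superior mesenteric artery and 5 higher and 29 lower in superior mesenteric artery; leaving out the dim 25% of genes, and averaging probe sets, each gave 5 higher there. Except for the threshold, the cause was not tested.

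Whether equal replicate numbers pair the samples could not be settled. After vessel means were removed, arrays of different vessels with the same number had a median correlation across genes of 0.0167 over 18 pairs. It was -0.0164 over 36 pairs with different numbers. Genes are not independent and some arrays carried other tissues, so these values show no clear pairing but do not exclude one. With the replicate number as a block, the counts were 0 for ascending against descending aorta, 23 for ascending aorta against superior mesenteric artery, 5 lower in coronary artery, 0 higher in descending aorta and 9 lower in superior mesenteric artery; the cause was not tested.

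Without the 3 arrays, 330 genes differed between ascending aorta and superior mesenteric artery, 21 were lower in coronary artery, and 13 were higher and 128 lower in superior mesenteric artery, than in each other vessel. With the lymphoid covariate the counts were 6 for ascending against descending aorta, 877 for ascending aorta against coronary artery, 255 for ascending aorta against superior mesenteric artery and 1015 for coronary artery against descending aorta; 2 genes were higher in ascending aorta, 90 lower in coronary artery, and 27 higher and 58 lower in superior mesenteric artery. The cause was not tested. The reversed list medians were these. Without ascending aorta replicate 1, B cell genes were at -0.345 against descending aorta and -0.293 against coronary artery, cell cycle genes at -0.0645 and -0.0154, fibroblast genes at 0.0229 against descending aorta and T cell genes at -0.151 against coronary artery. Without the 3 arrays the same medians were -0.277, -0.293, -0.1, -0.0154, 0.00218 and -0.151. With the covariate, B cell and cell cycle genes were at -0.0256 and -0.0295 in ascending against descending aorta, and T cell genes at 0.24 and 0.09 in coronary artery and descending aorta against superior mesenteric artery; the covariate holds the B and T cell genes themselves. Without superior mesenteric artery replicate 1, smooth muscle genes were at 0.214 in descending aorta against superior mesenteric artery. Leaving out other arrays moved these medians the other way, at most to 1.65 and 1.74 for B cell genes in ascending aorta against descending aorta and coronary artery, 0.465 and 0.451 for cell cycle genes and 1.51 for T cell genes against coronary artery, each without ascending aorta replicate 2, as was -1.23 for fibroblast genes against descending aorta. For smooth muscle genes it was -0.864, without superior mesenteric artery replicate 2.

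With each array left out in turn, the lowest and highest counts were 551 and 1825 among the 4 vessels, 0 and 3 for ascending against descending aorta, 251 and 768 for ascending aorta against coronary artery, 6 and 628 for ascending aorta against superior mesenteric artery, 324 and 1056 for coronary artery against descending aorta, 314 and 1292 for coronary against superior mesenteric artery, and 218 and 1361 for descending aorta against superior mesenteric artery. Counts against each other vessel ran from 153 to 254 higher and 0 to 47 lower in coronary artery, 0 to 3 higher in descending aorta, and 0 to 63 higher and 3 to 207 lower in superior mesenteric artery; they stayed at 0 and 0 by limma for both directions in ascending aorta and for lower in descending aorta (49, 39 and 52 genes at an unadjusted p under 0.05 in the full set). The highest count came without ascending aorta replicate 1 in each result but those on 1 aortic segment alone and on ascending against descending aorta. The lowest came without descending aorta replicate 2 among the vessels, for coronary artery against descending aorta and for descending aorta against superior mesenteric artery; without coronary artery replicate 3 for ascending aorta and superior mesenteric artery against coronary artery and for both coronary artery sets; without ascending aorta replicate 3 for ascending aorta against superior mesenteric artery; and without ascending aorta replicate 2 or 3 for both superior mesenteric artery sets, where leaving out superior mesenteric artery replicate 3 also gave 3 lower. Signal over background was not judged, since detection calls were not used here.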

Other observations

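All tests in this part were chosen after results were seen, as were the bounds set for them. Some values per array stood far from their vessel's others: in descending aorta replicate 1 the atrial genes Myl7 and Myl4, which enter the comparison with coronary artery, stood at 9.24 and 8.29, against 4.42 and 5.19 in replicate 2 and 4.86 and 4.88 in replicate 3. Superior mesenteric artery replicate 3 had a pancreatic acinar mean of 9.32.

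Ascending aorta replicate 1 stood apart from replicates 2 and 3: of 30 B cell and T cell genes, 100% were over 2-fold above both, against 5% of all genes, while 80% of 25 smooth muscle genes and 88.9% of 18 fibroblast genes were over 2-fold below. Lymphoid tissue taken with the vessel may account for part of it, and so might a superior mesenteric artery sample under the wrong label. With 0 at the other ascending aorta arrays and 1 at superior mesenteric artery, the array's median position was 1.42 over 98 genes higher in superior mesenteric artery (bootstrap 95% interval 1.13 to 1.77; 0.533 over the 21 whose correlation with the lymphoid mean is at or below 0, 1.25 over 28 with one up to 0.5 and 1.81 over 49 above that) and 0.923 over 311 genes lower there (0.852 over 167, 0.972 over 107 and 1.12 over 37 in the same order). Against this, the brown adipocyte mean of 5.86, compared only after the 1.42 was known, lay 1.22 above the highest superior mesenteric artery array, Ucp1 stood at 10.6 against at most 6.82 there, and Pcp4 at 4.90 against at least 7.69. These values go both ways, so a wrong label stays open and cannot be told apart from lymphoid tissue here. The bootstrap resampled genes of 1 array, which are not independent, so its interval does not measure the spread between samples.

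Cardiomyocyte genes were higher in coronary artery, a vessel that runs on and in heart muscle. Heart muscle taken with the artery is a candidate explanation, and Myl2 at 12.09 and Myl7 at 11.99 are among the abundant transcripts such tissue would bring. The list's median expression percentile within the coronary artery arrays was 98.4 over 30 genes, but a percentile sets different probe sets against each other and restates the difference between vessels, so it decides nothing. Heart muscle cannot be told apart here from cardiomyocyte transcripts made by cells of the artery itself, since no sample of heart muscle was analysed here.

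Mitochondrial genes were lower in superior mesenteric artery, as were brown adipocyte genes, and less brown adipose tissue around the artery may account for both. For the correlation within vessels, Cox7a1 and Cox8b were left out of the brown adipocyte mean. Its correlation with the oxidative phosphorylation mean was 0.689 over 12 arrays (permutation p = 0.104). It was 0.239 without ascending aorta replicate 1 (permutation p = 0.621) and -0.103 without descending aorta replicate 1 as well (permutation p = 0.775). Between coronary artery and descending aorta the lists differed in pattern: oxidative phosphorylation averaged 9.63 ± 0.083 and 9.64 ± 0.15, with brown adipocyte means of 5.39 and 7.03 over the whole list. The shared cardiomyocyte mean was 9.28 in coronary artery and 5.07 in descending aorta, and whether heart muscle sets the mitochondrial level there was not tested. With so few arrays the explanation cannot be told apart from a difference in the vessel wall, which was not tested.

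Position along the body axis is a hypothesis for the Hox genes, examined in the contrast of descending aorta and superior mesenteric artery against ascending aorta and coronary artery. Of 37 measured Hox genes 3 were higher (Hoxb5, Hoxb6 and Hoxc8) and 0 lower by limma, and 26 had a positive difference; without ascending aorta replicate 1 the numbers were 3, 0 and 26, and without the 3 arrays that carried another tissue 2, 0 and 24. All 3 had been called between coronary artery and descending aorta before the contrast was set, so it restates that comparison and gives no independent evidence. Hoxc8, at 5.16 in descending aorta against 3.15 in superior mesenteric artery and 2.83 and 2.87 in ascending aorta and coronary artery, passed through descending aorta. Hoxb6 was also lower in coronary artery than in superior mesenteric artery, at 3.67 against 5.29 (limma adjusted p = 0.0179; not past the threshold in 4 of 12 sets with 1 array left out), which argues against a difference of the descending aorta alone for that gene. The Hox genes of groups 1 to 5 averaged 4.04 in superior mesenteric artery and 4.14 in descending aorta, against 3.74 in ascending aorta and 3.52 in coronary artery. Position along the axis stays open, with no test here that is independent of the genes that prompted it.

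The real grouping of the 12 arrays into 4 groups of 3 was compared with 99 others, and it is itself counted among the 100. For genes differing among the vessels, only 1 of the 100, the real one, reached 942 (highest other 491), so chance can be excluded for a grouping of all 12 arrays. The share was small for genes higher in coronary artery (3 reached 212, highest other 219). There, 4 groupings reach 212 when the highest count of any 1 of the 4 groups is taken. For genes lower in coronary artery (3 reached 9, highest other 26) 5 groupings then reach 9. Shares of 4 and 5 in 100 drawn groupings cannot be told apart, so chance is left open for the size of both sets. The shared cardiomyocyte list, fixed before the data were examined, averaged 9.28 ± 0.202 in coronary artery. In the other vessels it averaged between 4.67 and 5.07, which argues against chance for the genes of that list. The shares were small too for genes lower in superior mesenteric artery (1 of 100; 16, highest other 3), higher in descending aorta (1; 3, highest other 1) and higher in superior mesenteric artery (2; 3, highest other 194). Only 2 of the 100 groupings keep the 3 coronary artery arrays together, however, so these shares do not exclude chance among the other 9 arrays. In another 100 groupings, the real one included, those 3 arrays stay together and the other 9 are regrouped. Of these, 5 reached 942 (highest other 2218), so chance cannot be excluded for how the other 9 arrays are grouped. The 4 above 942 all put ascending aorta replicate 1 with superior mesenteric artery replicates 2 and 3. The sets lower in superior mesenteric artery, higher in descending aorta and higher in superior mesenteric artery were each reached by 3 (highest other 79, 280 and 344). When the highest count of any 1 of the 3 regrouped groups was taken, a test added once these shares were known, 5 reached 16 genes lower and 5 reached 3 higher, so chance is left open for these sets. The coronary artery sets, whose own arrays stay together in this test, were each reached by 5 (highest other 234 higher and 17 lower). The 3 genes higher in descending aorta are also the 3 called between ascending and descending aorta, and for that count 7 of the 100 groupings reached 3, so chance cannot be excluded for the pairwise count. Chance cannot be excluded for the list tests, where 33 of 100 groupings called as many as the real 96 (lowest 46, highest other 120). Real counts of 0 by limma are reached by 100 of 100 groupings by construction, since no count lies below 0. For them the groupings decide nothing. These are the counts higher (highest other 213, with 49 genes at an unadjusted p under 0.05) and lower (highest other 23, with 39 genes) in ascending aorta and lower in descending aorta (highest other 3, with 52 genes). The groupings with 219 and 213 genes put ascending aorta replicate 1 with superior mesenteric artery replicates 2 and 3, which points to a structure of the samples. The grouping with 194 keeps the 3 coronary artery arrays together, in the place of superior mesenteric artery, so it counts coronary artery genes.

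Splits of the 6 arrays of a pair into 3 and 3 number 10, too few for a share under 0.05. The real count and the highest other were 3 and 0 for ascending against descending aorta, 493 and 0 for ascending aorta against coronary artery, 627 and 0 for coronary artery against descending aorta, 645 and 1 for coronary against superior mesenteric artery, and 639 and 0 for descending aorta against superior mesenteric artery, with 1 of 10 splits reaching the real count in each. For ascending aorta against superior mesenteric artery they were 35 and 911, with 2 of 10 splits reaching it. The split with 911 genes sets ascending aorta replicate 1 and superior mesenteric artery replicates 2 and 3 against the rest, which points to a structure of the samples.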
